A study of Mus musculus with 12 samples.

How the data were processed

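Total RNA from PKSV-PCT mouse proximal tubule cells was measured on 12 Illumina Mouse WG-6 v2.0 bead arrays, 3 for each combination of SHBG variant (human wild-type or S42L) and androgen (100 nM testosterone or DHT for 24 h). The labels also give 3 days in steroid-free medium, worded so that it follows the hormone, and the true order stays uncertain. Per the labels' protocols, the lines were cloned by limiting dilution and picked by the SHBG they secreted, and the medium held dexamethasone, which itself acts on many steroid-responsive genes. There was no untreated group. Groups and replicate numbers came from the sample titles, and chip and position from the array names. Each chip held 6 arrays, chip 1 those with DHT and chip 2 those with testosterone, with S42L cells in the upper and wild-type cells in the lower positions of both.

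The deposited table gives, per the file headers, an average bead signal per probe and array, an intensity on a linear scale that was neither background-subtracted nor normalized between arrays. It also gives a detection p-value per probe and array, deposited with the signals, which compares the probe with negative control beads. BeadStudio is named in the submitters' processing notes, with no version given in the sources used here. A second table with the authors' processed intensity values was used as an alternative only. Each of its columns had a rank correlation of 1 with the signals of its own array and of at most 0.865 with any other. Its medians were 6.8 on 11 arrays and 6.9 on S42L DHT replicate 2, and its minimum was -30.1 on every array. From its values it is linear, background-subtracted, normalized to near equal quantiles and not centred by gene, but no source states these steps, and which background method was used stays unknown.

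The signals were background-corrected from the detection p-values, raised by an offset of 16, quantile-normalized and put on a log2 scale with neqc in limma 3.58.1 (R 4.3.3). Quantile normalization gives every array the same distribution, so a shift of most transcripts in 1 direction between the lines would be removed, and median scaling was therefore an alternative. Probes with a detection p under 0.05 on at least 3 of 12 arrays were tested, 19480 of 45281. Per array 17314 to 19204 probes were detected. The median signal of undetected probes was 108.9 to 129.5 against a median of 116.5 to 139.8 for all probes. Most probes were undetected on each array, so these medians lie close by that alone. A small fold of a dim probe can be compressed by background. The number of arrays limits the precision, with 95% confidence intervals reaching, in the median, 0.315 log2 units to either side for a contrast of 3 against 3 arrays, 0.223 over both androgens and 0.446 for the interaction.

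Gene names came from the platform annotation, in which 34885 probes have 1 symbol, 18 have several and 10378 have none here. Unnamed probes were tested but not named. Through gene identifiers, 34807 annotation entries matched current RefSeq entries, and 0 had another symbol. A gene's value is that of its probe with the highest mean signal. Where a probe was undetected on all arrays of a group, its difference is given as at least N-fold. That bound is the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the probe's value and the lowest value of any detected probe. It stands in place of the fitted change. Over both androgens a bound is given where the gene was undetected in at least 1 of the line's 2 groups, with every array of the dim line entering in this way.

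limma's lmFit and eBayes were fitted with 1 coefficient per group over all 12 arrays (8 residual and 4.36 prior degrees of freedom). There were 6 two-sided contrasts, wild-type minus S42L under each androgen and averaged, DHT minus testosterone in each line, and the interaction. P-values were adjusted by Benjamini-Hochberg over probes, and a probe was called at an adjusted p under 0.05. Additive chip effects cancel in the variant contrasts and the interaction but not in the hormone contrasts. The 26 gene lists, the tests and the alternatives were fixed before the data were examined, apart from those stated to be later. Of 969 list genes, 868 were found by symbol, 19 by a synonym and 82 were not named in the probe table and are not analysed here, among them some genes named in advance. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over lists, and with an estimated correlation and fry as alternatives. At the preset correlation 3, 7 and 6 lists were called in the variant contrasts under DHT, under testosterone and over both, 1 and 0 in the hormone contrasts and 1 in the interaction. With an estimated correlation these were 2, 2, 2, 0, 0 and 1. fry's direction test, which compares no list with other genes, called 19, 15, 18, 1, 0 and 1.

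Genes were named by a rule fixed in advance. It takes the 10 highest and 10 lowest called genes of each contrast (5 and 5 for the variant contrast under 1 androgen, and all called genes where calls were under 20), and of each list up to 4 measured members with the smallest adjusted p. Odc1, Gusb, Lrp2, Fkbp5, Tsc22d3, Kap and Shbg were always named. Dok3 in the comparison of contrasts and members of the ATF4 target list were named after their values were seen. On simulated data of 19480 probes, a log2 change of 1 was recovered for 88.1% to 91% of changed probes in single contrasts, 98.5% over both androgens and 59.7% in the interaction. A change of 0.5 was recovered for 13.4% to 23.9%, 59.7% and 5.97%, with 2 to 15 false calls. In each comparison only 67 probes were changed by 0.5, 67 by 1 and 66 by 2. The real variant contrasts called 23% to 37.8% of probes, which loosens the adjusted threshold. The recovered shares therefore do not carry over to those contrasts. A simulated list of 30 genes shifted by 0.3 was called over both androgens and in the interaction, and 0 of 20 unshifted lists were. The simulated genes varied independently of each other, so this does not show how often the list test calls correlated genes.

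Alternatives were normexp with an offset of 50, no background correction, median scaling, the authors' values (with an offset of 16 before log2), no probe filter and a stricter one (detection p under 0.01 on all arrays of a group). Others were the replicate number as a block, trend with robust variance, array weights, 1 probe per gene, at least 2-fold, adjusted p under 0.01, only the 6 arrays compared, additive variant and chip terms, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.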

Results

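The data are 12 Illumina mouse whole-genome bead arrays of total RNA from PKSV-PCT cells, an immortalized mouse line of the kidney's proximal convoluted tubule. Sublines had been made that stably express human sex hormone-binding globulin (SHBG), the plasma carrier of androgens and estradiol, either as the wild-type protein or as the S42L mutant with no measurable steroid binding. Each line received 100 nM testosterone or 100 nM 5α-dihydrotestosterone (DHT) for 24 h, which gives 4 groups of 3 arrays. The series concerns whether SHBG retained inside tubule cells alters androgen action. The mean signal per array ran from 560.2 to 707.4 and the median signal from 116.5 to 139.8. Between 17314 and 19204 of the 45281 probes were detected per array, and 19480 probes, standing for 10340 named genes, were tested. The mouse probe for Shbg was below background on all 12 arrays. Whether it can read the human transgene was not tested, so it checks nothing about the labels. Kap, the kidney androgen-regulated protein gene, was likewise detected on 0 of 12 arrays. No label says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The lines were cloned and the labels name no separate clones of a variant, so SHBG variant and clone cannot be told apart. All DHT arrays lay on 1 chip and all testosterone arrays on the other.

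The comparison of wild-type with S42L cells over both androgens addressed what steroid-binding SHBG changes in androgen-treated tubule cells. Log2 fold changes are wild-type minus S42L, with their SE, from 6 arrays against 6. Transcripts lower in wild-type cells included Slc39a4, a zinc importer detected on 4 of 6 wild-type arrays, at -5.13 ± 0.12, and Dcn, the proteoglycan decorin, at -4.79 ± 0.10. Osr2, a zinc-finger transcription factor, stood at -4.34 ± 0.10, Capsl at -4.20 ± 0.09, the growth factor receptor Fgfr2 at -3.63 ± 0.08 and the cytochrome P450 Cyp2d22 at -3.59 ± 0.10. Undetected on all 6 wild-type arrays, and so without a rank among these, were Ppic, encoding cyclophilin C, at least 24.6-fold lower (adjusted p = 2.4e-12), and Cfap58, a cilium-associated gene, at least 7.54-fold lower (adjusted p = 1.9e-11). Nme5, of the nucleoside diphosphate kinase family, and Xlr4a were undetected on the 3 DHT arrays and detected on 1 of 3 testosterone arrays of that line, and were at least 14.2-fold (adjusted p = 2.4e-11) and 9.61-fold lower (adjusted p = 1.9e-11).

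Transcripts higher in wild-type cells included Cox6a2, the heart and muscle form of a cytochrome c oxidase subunit, at 3.32 ± 0.18, although it was detected on 2 of 6 S42L arrays, which leaves its rank uncertain. B4galnt2, a glycosyltransferase, stood at 2.98 ± 0.11, Tlcd2 at 2.75 ± 0.12, the annexin Anxa8 (detected on 5 of 6 S42L arrays) at 2.40 ± 0.11 and Tnfaip2 at 2.32 ± 0.12. Also higher were Timd2, a ferritin receptor detected on 3 of 6 S42L arrays, at 2.24 ± 0.14, the alcohol dehydrogenase Adh7 at 2.23 ± 0.09, the integrin subunit Itgb7 at 2.13 ± 0.09 and the retinol dehydrogenase Rdh12 at 2.13 ± 0.11. Prune2, detected on 2 of 3 S42L arrays under DHT and 0 of 3 under testosterone, was at least 7.77-fold higher (adjusted p = 1.7e-09). Adjusted p for these 20 genes ran from 2.4e-12 to 1.8e-07. Of genes named in advance, Lrp2, the endocytic receptor megalin, was lower at -0.50 ± 0.08 (adjusted p = 0.00041) and Tsc22d3, a glucocorticoid-induced leucine zipper gene, at -0.34 ± 0.09 (adjusted p = 0.0086). Odc1, ornithine decarboxylase, differed by -0.11 ± 0.09 (adjusted p = 0.37), Fkbp5, a steroid-induced cochaperone, by -0.01 ± 0.08 (adjusted p = 0.93) and Gusb, β-glucuronidase, by -0.10 ± 0.08 (adjusted p = 0.39). Lrp2 probes detected on 0 and on 2 of 12 arrays were not tested. For Gusb, 2 other probes were called in the opposite direction.

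Across the array, limma with Benjamini-Hochberg adjustment called 7371 of 19480 probes (37.8%), 3752 higher and 3619 lower in wild-type cells, or 2018 and 2128 genes. At least 2-fold differences numbered 115 genes higher and 248 lower. With arrays scaled to a common median in place of quantile normalization, 6670 probes were called, 2005 higher and 4665 lower, so that 30.1% in place of 50.9% of called probes were higher. That scaling moved the median of all probes to -0.076 here and to -0.11 under testosterone.

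Proliferation genes were higher in wild-type cells as a group. Of 41 measured cell cycle and E2F target genes, 26 were higher, 1 was lower and 14 were not called (28 and 1 adjusted over the list alone). The G1 cyclins Ccnd1 (0.82 ± 0.07) and Ccnd2 (1.12 ± 0.12) and the replication helicase subunit Mcm3 (0.74 ± 0.08) were higher, whereas Ccne1, cyclin E1, was the lower member (-0.96 ± 0.10). The list median was 0.32, and camera gave adjusted p = 2.14e-06, or adjusted p = 0.0346 with an estimated correlation. Immediate early genes, which respond quickly to growth signals, were higher in 14 and lower in 3 of 24, with 7 not called (14 and 3 adjusted over the list alone). Dusp5 (1.22 ± 0.09) and Dusp4 (0.96 ± 0.09), phosphatases of MAP kinases, and Fosl2 (0.50 ± 0.08) were higher, and Egr3 was at least 2.16-fold higher. Camera gave adjusted p = 0.0127, and adjusted p = 0.172 with an estimated correlation. Among 28 sterol and fatty acid synthesis genes, 11 were higher, 2 lower and 15 not called (12 and 2 adjusted over the list alone). Acss2, an acetyl-CoA synthetase (0.79 ± 0.08), the transcription factor gene Srebf2 (0.60 ± 0.07) and Hsd17b7 (0.48 ± 0.08) were higher, and the desaturase Scd1 was lower (-0.54 ± 0.07). This list had camera adjusted p = 0.0349, and adjusted p = 0.157 with an estimated correlation. The sterol call also ended without S42L testosterone replicate 2 (adjusted p = 0.0525), without wild-type testosterone replicate 2 (0.0549) and with the mean of a gene's probes (0.0555), in a range of 0.00638 to 0.157 over the alternatives.

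Epithelial junction genes were lower in wild-type cells as a group. Of 29 epithelial junction genes, 15 were lower, 1 higher and 13 not called (15 and 2 adjusted over the list alone). Cldn2, the paracellular cation channel claudin-2 of the proximal tubule, stood at -3.17 ± 0.10, E-cadherin Cdh1 at -1.87 ± 0.09, the splicing regulator Esrp1 at -1.30 ± 0.07 and cadherin-6, Cdh6, at -0.86 ± 0.09. Camera gave adjusted p = 0.000727 for the list, and adjusted p = 0.0346 with an estimated correlation. Without Cldn2, left out after its value was seen, 24 of 28 members were below 0 and camera gave adjusted p = 0.00329, or 0.0422 with an estimated correlation. Of 21 proximal tubule markers, 11 were lower, 4 higher and 6 not called (11 and 4 adjusted over the list alone). The peptidase Mme (-1.32 ± 0.10), Cyp4b1 (-1.30 ± 0.09) and the cubilin partner Amn (-0.82 ± 0.07) were lower, and Havcr1, the kidney injury molecule KIM-1, was higher (1.58 ± 0.09). The list had camera adjusted p = 0.0349, and adjusted p = 0.142 with an estimated correlation. Of 45 endocytosis and lysosome genes, 16 were lower, 5 higher and 24 not called (16 and 5 adjusted over the list alone). The lysosomal proteases Ctsh (-1.45 ± 0.14), Ctsa (-1.73 ± 0.17) and Tpp1 (-0.82 ± 0.09) were lower, and the endosome recycling gene Ehd1 was higher (0.92 ± 0.15). The list had camera adjusted p = 0.0458, and adjusted p = 0.157 with an estimated correlation. Median scaling ended the proximal tubule call (adjusted p = 0.063) and the endocytosis call (0.119), and testing all probes ended the proximal tubule call (0.0993), in ranges of 0.0229 to 0.142 for the proximal tubule and 0.0116 to 0.157 for endocytosis. The endocytosis call also ended with the mean of a gene's probes (0.0555) and without any of 7 single arrays, namely DHT S42L replicates 2 (0.0685) and 3 (0.0515), DHT wild-type replicates 1 (0.0552) and 2 (0.0541), testosterone S42L replicates 1 (0.0667) and 2 (0.0525) and testosterone wild-type replicate 3 (0.0812).

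**Figure D1:**
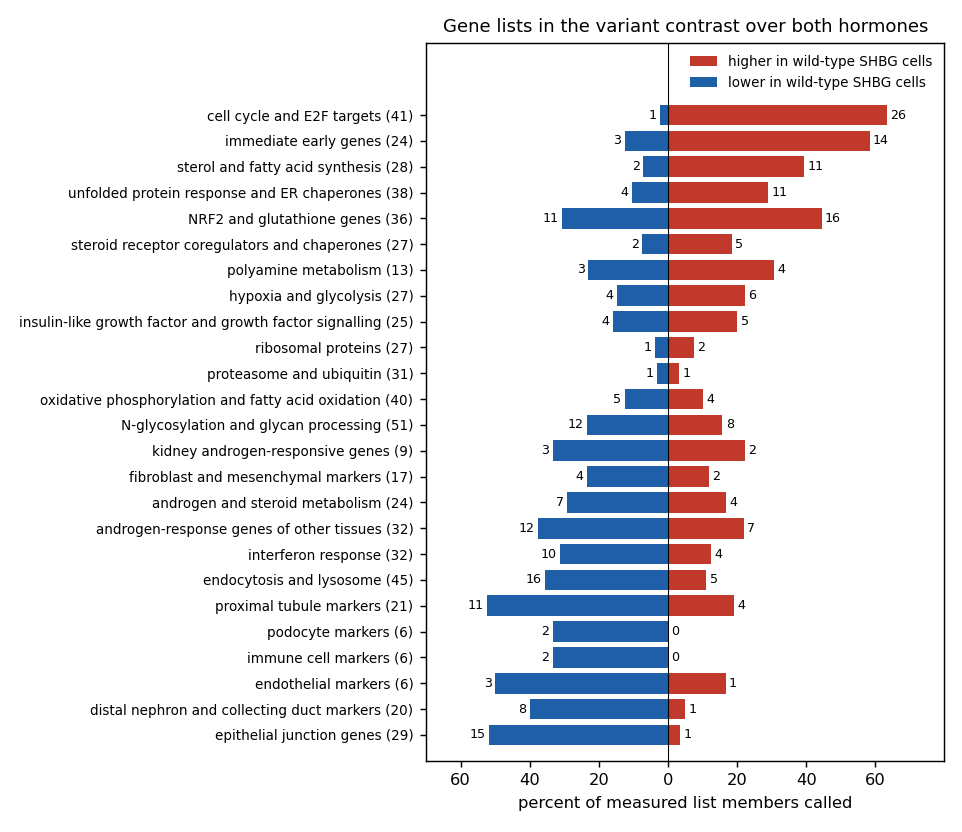
Bars give the percent of each list's measured genes (number in brackets) called higher (right) or lower (left) in wild-type SHBG cells over both androgens, with the number of genes at the bar's end, for the 25 lists tested. Cell cycle genes lie mostly to the right (26 of 41) and epithelial junction genes mostly to the left (15 of 29).

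The other lists were not called by camera in this comparison, and a list with no separate count had the same count adjusted over the list alone. Kidney androgen-responsive genes were higher in 2 and lower in 3 of 9, with Timd2 at 2.24, the alcohol dehydrogenase Adh1 at 0.88 ± 0.09, Cyp4b1 at -1.30 and the dipeptidase Cndp2 at -0.33 ± 0.07 (camera adjusted p = 0.752). Their median was -0.11, their mean 0.08 and the test's direction downward. Androgen-response genes of other tissues were higher in 7 and lower in 12 of 32 (9 and 12 adjusted over the list alone, camera adjusted p = 0.648). Tmprss2, a membrane serine protease (-1.35 ± 0.09), and the metallothioneins Mt1 (-0.76 ± 0.07) and Mt2 (-1.16 ± 0.12) were lower, and the transporter Abcc4 was higher (1.16 ± 0.08). Androgen and steroid metabolism genes were higher in 4 and lower in 7 of 24 (camera adjusted p = 0.531), with the glucuronosyltransferases Ugt1a6a (-0.91 ± 0.09) and Ugt1a10 (-0.76 ± 0.08) and Hsd17b11 (-0.85 ± 0.09) lower and Cyp3a13 (0.64 ± 0.10) higher. Steroid receptor coregulators and chaperones were higher in 5 and lower in 2 of 27 (camera adjusted p = 0.501), with Fhl2 (0.92 ± 0.08), Hspa4 (0.57 ± 0.09) and Hsp90aa1 (0.51 ± 0.08) higher and the demethylase Kdm1a (-0.60 ± 0.08) lower. Polyamine genes were higher in 4 and lower in 3 of 13 (camera adjusted p = 0.648), with the arginase Arg2 (0.90 ± 0.11), Dhps (0.44 ± 0.08) and Amd2 (0.32 ± 0.08) higher and the lysosomal polyamine exporter Atp13a2 (-0.97 ± 0.10) lower. N-glycosylation genes were higher in 8 and lower in 12 of 51 (9 and 12 adjusted over the list alone, camera adjusted p = 0.811). The branching enzyme Mgat4a (0.96 ± 0.07) and Pmm1 (0.76 ± 0.09) were higher, and the sialyltransferase St6gal1 (-1.03 ± 0.08) and Pmm2 (-0.80 ± 0.11) lower.

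Among stress and metabolic lists, unfolded protein response and ER chaperone genes were higher in 11 and lower in 4 of 38, led by Trib3 (1.48 ± 0.07), Ddit3, encoding CHOP (1.27 ± 0.08), Ero1b (1.18 ± 0.08) and the glutathione-degrading enzyme gene Chac1 (1.12 ± 0.08), with camera adjusted p = 0.113. NRF2 and glutathione genes were higher in 16 and lower in 11 of 36 (camera adjusted p = 0.471), with heme oxygenase Hmox1 (2.11 ± 0.18), the cystine transporter Slc7a11 (1.21 ± 0.08) and Abcc4 higher and the glutathione peroxidase Gpx3 (-1.34 ± 0.07) lower. Interferon response genes were higher in 4 and lower in 10 of 32 (6 and 10 adjusted over the list alone, camera adjusted p = 0.113), with Ifit3 (-2.05 ± 0.09), Irgm2 (-1.50 ± 0.10), Gbp2 (-1.36 ± 0.10, detected on 4 of 6 wild-type arrays) and Parp14 (-1.30 ± 0.08) lower. Hypoxia and glycolysis genes were higher in 6 and lower in 4 of 27 (camera adjusted p = 0.642), with the collagen hydroxylase subunit P4ha1 (0.75 ± 0.11), the glucose transporter Slc2a1 (0.41 ± 0.08) and the prolyl hydroxylase Egln3 (0.39 ± 0.07) higher and Ndrg1 (-0.57 ± 0.10) lower. The mean of Egln3 joined calls of opposite direction, -0.43 under DHT and 1.20 under testosterone, and the list median was -0.11 under DHT and 0.19 under testosterone. Oxidative phosphorylation and fatty acid oxidation genes were higher in 4 and lower in 5 of 40 (3 and 5 adjusted over the list alone, camera adjusted p = 0.752), with Cyc1 (0.39 ± 0.07) and Idh3a (0.53 ± 0.12) higher and Atp5o (-0.53 ± 0.08) and Ppargc1a (-0.65 ± 0.14) lower. Growth factor signalling genes were higher in 5 and lower in 4 of 25 (camera adjusted p = 0.902), with Hbegf (1.20 ± 0.09) higher and Fgfr2, Bmp4 (-1.20 ± 0.11) and Erbb2 (-0.56 ± 0.08) lower. Their median was 0.06 and their mean -0.10, with the test's direction downward. Ribosomal protein genes were higher in 2 and lower in 1 of 27 (1 and 1 adjusted over the list alone, camera adjusted p = 0.752), namely Rpl30 (0.29 ± 0.06), Rps6 (0.20 ± 0.06) and Rpl22 (-0.70 ± 0.07). Proteasome and ubiquitin genes were higher in 1, Psmc1 (0.26 ± 0.08), and lower in 1, Ufd1 (-0.32 ± 0.08), of 31 (0 and 0 adjusted over the list alone, camera adjusted p = 0.752). With median scaling the medians of the following lists fell on the other side of 0, namely unfolded protein response (0.11 and -0.0012), NRF2 (0.05 and -0.0063), hypoxia (0.06 and -0.0074), coregulators (0.01 and -0.07), growth factor signalling (0.06 and -0.04), proteasome (0.02 and -0.0073) and fibroblast markers (0.0083 and -0.14). That scaling also lowered the median of all probes, from 0.016 to -0.076, and relative to it the medians were 0.074 for unfolded protein response, 0.069 for NRF2, 0.068 for hypoxia, 0.005 for coregulators, 0.04 for growth factor signalling, 0.068 for proteasome and -0.06 for fibroblast genes.

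Markers of other cell types were mostly lower or not called in wild-type cells. Distal nephron and collecting duct markers were higher in 1 and lower in 8 of 20 (camera adjusted p = 0.113), with the sodium channel subunit Scnn1a at least 5.67-fold lower, uromodulin, Umod, at least 1.24-fold lower, kidney cadherin Cdh16 at -0.54 ± 0.06 and the keratin Krt7 at -0.49 ± 0.08. Fibroblast and mesenchymal markers were higher in 2 and lower in 4 of 17 (5 and 4 adjusted over the list alone, camera adjusted p = 0.845). Dcn and the collagen Col5a1 (-0.70 ± 0.10) were lower, and the repressor Zeb1 (0.71 ± 0.08) and Fbln2 (at least 1.67-fold) higher. The median of that list was 0.0083, its mean -0.23 and the test's direction downward. Podocyte markers were lower in 2 of 6 (camera adjusted p = 0.501), namely Synpo at -1.89 ± 0.07 and Clic3, at least 1.27-fold lower. Endothelial markers were higher in 1 and lower in 3 of 6 (camera adjusted p = 0.288), with Egfl7 (-1.09 ± 0.11), Flt1 (-0.80 ± 0.09) and Esam (-0.37 ± 0.11, detected on 5 of 6 wild-type arrays) lower and Kdr at least 1.25-fold higher. Immune markers were lower in 2 of 6, Csf1r (-0.996 ± 0.10) and Coro1a (at least 1.14-fold), with 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.345). Of 3 measured Y-linked genes, too few for the set test, Eif2s3y (0.46 ± 0.08) and Kdm5d (0.45 ± 0.13) were higher and Uty differed by 0.11 ± 0.16 (adjusted p = 0.63).

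Under DHT alone, from 3 arrays against 3, the genes at the extremes were Cox6a2 (3.27 ± 0.26), Prune2 (3.05 ± 0.16), B4galnt2 (3.05 ± 0.16), Tlcd2 (2.88 ± 0.16) and Timd2 (2.58 ± 0.20) on the higher side. On the lower side were Slc39a4 (-5.04 ± 0.17), Dcn (-4.78 ± 0.15), Osr2 (-4.53 ± 0.14), Ppic, at least 23.7-fold lower, and Nme5, at least 14.7-fold lower. Cox6a2 and Timd2 were detected on 1 and Prune2 on 2 of 3 S42L arrays, and Slc39a4 on 2 of 3 wild-type arrays, so the order of these genes is uncertain. Cell cycle genes were higher in 15 and lower in 1 of 41 (19 and 1 adjusted over the list alone), including Cenpf (0.78 ± 0.11) and Gins1 (0.86 ± 0.14), with camera adjusted p = 1.22e-05 and adjusted p = 0.0335 with an estimated correlation. Junction genes were lower in 8 of 29 (8 adjusted over the list alone), including Marveld3 (-1.06 ± 0.16), with camera adjusted p = 0.000664 and adjusted p = 0.0335 with an estimated correlation. Immediate early genes were higher in 9 and lower in 2 of 24 (10 and 2 adjusted over the list alone), including Egr1 (0.60 ± 0.10), with camera adjusted p = 0.011 and adjusted p = 0.211 with an estimated correlation. Hypoxia and glycolysis genes were higher in 2 and lower in 6 of 27 (2 and 6 adjusted over the list alone), with a median of -0.11, and the list was not called (camera adjusted p = 0.325). In all, 4474 probes were called, 2196 higher and 2278 lower. Median scaling called 3628, 1208 higher and 2420 lower, so 33.3% in place of 49.1% were higher. Uncalled here (camera adjusted p = 0.0552), the unfolded protein response list was called with normexp (0.0324), no background correction (0.0299), median scaling (0.0243), no probe filter (0.0234), the stricter filter (0.0405) and the mean of a gene's probes (0.0331) and without S42L replicate 1 (0.0418), wild-type replicate 1 (0.0387) or wild-type replicate 2 (0.0437), in a range of 0.0234 to 0.129. The proximal tubule list (0.058) was called with normexp (0.0417) and no background correction (0.0358) and without S42L replicate 1 (0.0446), and the endocytosis list (0.0932) with no probe filter (0.0371), in ranges of 0.0358 to 0.274 and 0.0371 to 0.197.

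Under testosterone alone, from 3 arrays against 3, Cox6a2 (3.38 ± 0.26), B4galnt2 (2.92 ± 0.16), Tlcd2 (2.61 ± 0.16), Anxa8 (2.58 ± 0.15) and Prune2, at least 7.72-fold, were the highest in wild-type cells. Slc39a4 (-5.21 ± 0.17), Dcn (-4.80 ± 0.15), Osr2 (-4.16 ± 0.14), Nme5 (fitted -4.10 ± 0.15) and Ppic, at least 25.4-fold lower, were at the other end. Nme5 was detected on 1 and Slc39a4 on 2 of 3 wild-type arrays, and Cox6a2 on 1 and Anxa8 on 2 of 3 S42L arrays, so the order of these genes is uncertain. Cell cycle genes were higher in 18 and lower in 1 of 41 (22 and 1 adjusted over the list alone), including Aurka (0.78 ± 0.13), with camera adjusted p = 4.79e-06 and adjusted p = 0.0488 with an estimated correlation. Junction genes were lower in 9 of 29 (9 adjusted over the list alone), with camera adjusted p = 0.00193 and adjusted p = 0.0488 with an estimated correlation. Sterol genes were higher in 12 and lower in 2 of 28 (13 and 2 adjusted over the list alone), with Acss2 at 0.93 ± 0.12 and camera adjusted p = 0.0155, and adjusted p = 0.103 with an estimated correlation. Proximal tubule markers were lower in 9 and higher in 3 of 21 (11 and 3 adjusted over the list alone), including the water channel Aqp1 (-1.34 ± 0.15) and the amino acid transporter Slc7a9 (-0.96 ± 0.12), with camera adjusted p = 0.0254, and adjusted p = 0.103 with an estimated correlation. Immediate early genes were higher in 8 and lower in 2 of 24 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0206, and adjusted p = 0.222 with an estimated correlation). Hypoxia and glycolysis genes were higher in 6 and lower in 1 of 27 (6 and 1 adjusted over the list alone), with Egln3 (1.20 ± 0.10), P4ha1 (0.98 ± 0.15), Egln1 (0.70 ± 0.17) and Slc2a1 (0.57 ± 0.11) higher, camera adjusted p = 0.0254, and adjusted p = 0.293 with an estimated correlation. Distal nephron markers were lower in 6 and higher in 1 of 20 (7 and 1 adjusted over the list alone), with Scnn1a, detected on 1 of 3 wild-type arrays, at -2.59 ± 0.19, camera adjusted p = 0.0478, and adjusted p = 0.136 with an estimated correlation. In all, 4636 probes were called, 2236 higher and 2400 lower. Without S42L replicate 2 these were 3103, 1424 higher and 1679 lower, and with array weights 8907, 4565 higher and 4342 lower. Median scaling called 4187, 899 higher and 3288 lower (21.5% in place of 48.2% higher), and relative to its shift in all probes the list medians were 0.38 for cell cycle, 0.35 for immediate early, 0.29 for sterol, 0.23 for hypoxia, -0.22 for junction, -0.24 for distal nephron and -0.51 for proximal tubule genes. It ended the proximal tubule call (adjusted p = 0.061) and the distal nephron call (0.0964), and the immediate early call ended without wild-type testosterone replicate 2 (0.0737), in ranges of 0.017 to 0.103, 0.022 to 0.136 and 0.00328 to 0.222 respectively. The distal nephron call also ended without S42L replicate 1 (0.0589), wild-type replicate 1 (0.136) or wild-type replicate 3 (0.0692), with either other probe filter (0.0718 and 0.0658) and with the authors' values (0.0608), while the endocytosis list (0.0506) was called with normexp (0.0409), no background correction (0.0348), no probe filter (0.0215) and the stricter filter (0.0475) and without S42L replicate 2 (0.0464) or 3 (0.0474) or wild-type replicate 1 (0.045) or 2 (0.036), in a range of 0.0215 to 0.158.

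Genes that differed between the lines under DHT mostly differed in the same direction under testosterone. Slc39a4, Dcn and Fgfr2 lay near the diagonal at the lower end and Cox6a2 and B4galnt2 at the upper end. Both contrasts called 854 genes higher, where independent lists would share 144, and 1072 genes lower, where they would share 193. Opposite calls were made for 2 genes, Egln3 (-0.43 ± 0.10 under DHT and 1.20 ± 0.10 under testosterone) and Dok3, an adaptor of tyrosine kinase signalling (0.73 ± 0.12 and -0.42 ± 0.12), detected on 2 of 3 S42L DHT and 1 of 3 wild-type testosterone arrays. Of 3342 genes called under either androgen, 97.5% had the same sign under both. Across 10340 genes, which are not independent replicates, Pearson's r was 0.882 and Spearman's rho 0.801, with a jackknife SE over arrays of 0.027 for r.

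**Figure D2:**
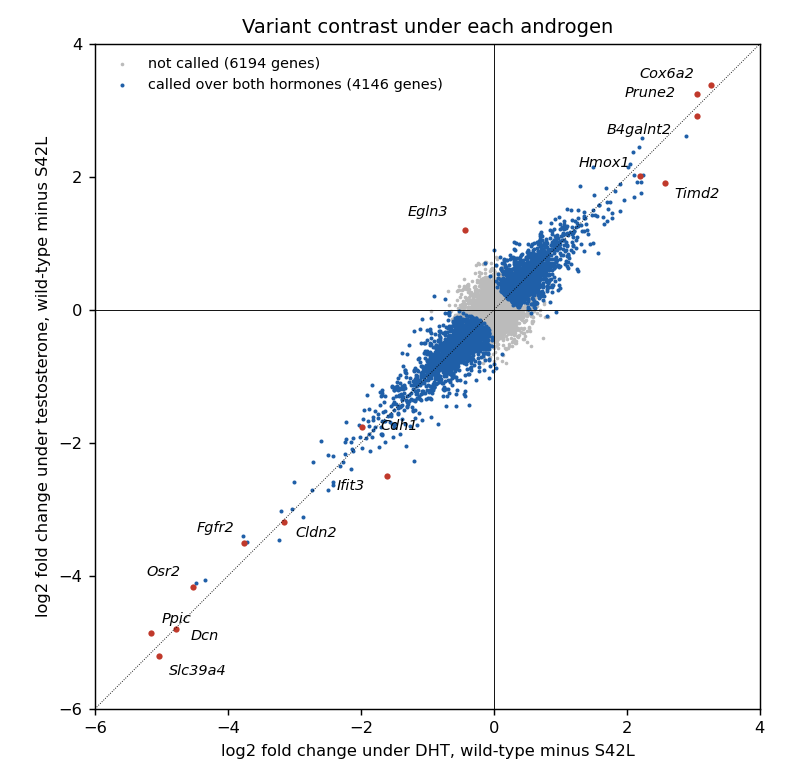
Each point is 1 gene, with the log2 fold change of wild-type over S42L cells under DHT (x axis) and under testosterone (y axis), from 3 arrays against 3 each; blue genes were called over both androgens (4146), grey ones were not (6194), red ones are labelled, and genes undetected in a group stand at their fitted values. Most genes lie along the dotted line of equal change, whereas Egln3 lies at -0.43 and 1.20.

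The comparison of DHT with testosterone within wild-type SHBG cells addressed whether the androgens differ at the same dose and time. DHT is testosterone with its 4,5 double bond reduced. Genes higher under DHT were Exosc2, an RNA exosome subunit (1.20 ± 0.17, adjusted p = 0.036), Dok3 (0.83 ± 0.12, adjusted p = 0.034, detected on 1 of 3 testosterone arrays) and the lysophospholipid acyltransferase Lpcat2, at least 1.52-fold (adjusted p = 0.049). Genes lower under DHT were Tpt1, a translationally controlled tumour protein gene (-1.15 ± 0.15, adjusted p = 0.021), Egln3 (-1.02 ± 0.10, adjusted p = 0.0044), the 14-3-3 protein gene Ywhae (-1.01 ± 0.16, adjusted p = 0.049) and the ER-phagy receptor gene Retreg3, at least 1.48-fold (adjusted p = 0.049). The Tpt1 probe was dim, at log2 5.329 to 5.602 under DHT and 6.511 to 6.695 under testosterone. The lowest value of any detected probe on these arrays was 5.061 to 5.171. Of 27 hypoxia and glycolysis genes, 1 fell, 0 rose and 26 were not called (6 fell and 0 rose adjusted over the list alone). Their median was -0.20, with Ankrd37 at -0.97 ± 0.16 (adjusted p = 0.053) and Eno2, neuronal enolase, at -0.55 ± 0.13 (adjusted p = 0.13). Camera gave adjusted p = 2.12e-06 for the list, and adjusted p = 0.248 with an estimated correlation. Without Egln3, left out after its value was seen, camera gave adjusted p = 5.33e-05, and adjusted p = 0.444 with an estimated correlation. The other 24 lists were not called. Limma called 14 of 19480 probes, 4 higher and 10 lower, while 2313 had an unadjusted p under 0.05. Leaving out single arrays gave 4 calls (wild-type DHT replicate 1, or testosterone replicate 3), 6 (DHT replicate 3, or testosterone replicate 1) or 8 (DHT replicate 2), and without testosterone replicate 2 there were 14, 7 higher and 7 lower, of which 5 were among the 14 with all arrays. Using only the 6 arrays compared gave 0 calls, the authors' values 4, all lower, and array weights 1844, and 0 of the 7 genes named here were called in every alternative. Without testosterone replicate 3 the immediate early list was called (camera adjusted p = 0.00173, in a range of 0.00173 to 0.971). Hormone and chip cannot be told apart.

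In S42L cells, DHT against testosterone addressed the same question without steroid binding by SHBG. Genes higher under DHT were Unc13a, a vesicle priming gene, at least 2.04-fold (adjusted p = 0.0085), the glutamate receptor subunit Grik5 (0.65 ± 0.11), Egln3 (0.61 ± 0.10) and the glycolytic aldolase Aldoc (0.55 ± 0.10). Egr1, an immediate early transcription factor, was the lowest under DHT (-1.18 ± 0.10, adjusted p = 0.00097). Also lower were Erich4 (-1.16 ± 0.19), the glucose-6-phosphatase catalytic subunit G6pc2 (-1.15 ± 0.16), Bnip5 (-1.13 ± 0.17), the selenium carrier Selenop (-1.08 ± 0.16) and the GABA transporter Slc6a13 (-1.06 ± 0.15). Ifit3, an interferon-induced gene (-0.88 ± 0.13), Hspa5, the ER chaperone BiP (-0.88 ± 0.16), Tm9sf3 (-0.86 ± 0.14) and the hydroxyproline dehydrogenase Prodh2 (-0.86 ± 0.15) were lower too. The Hspa5 probe was dim, at log2 5.63 to 6.048 under DHT and 6.552 to 6.865 under testosterone. Under DHT, Selenop and Prodh2 were detected on 1 and Erich4 and Tm9sf3 on 2 of 3 arrays. Adjusted p for the genes without their own value ran from 0.022 to 0.0455. Of the lists, hypoxia and glycolysis had 2 genes higher and 0 lower of 27 (2 and 1 adjusted over the list alone), namely Egln3 and Aldoc. Interferon response had 2 lower of 32 (2 adjusted over the list alone), Ifit3 and the class I antigen H2-K1 (-0.77 ± 0.14). Immediate early genes had 1 lower of 24 (4 adjusted over the list alone) and unfolded protein response 1 of 38 (1 adjusted over the list alone). Camera called 0 of 25 lists at a preset correlation and 0 with an estimated one, and fry called 0. The interaction test did not call Egr1 (0.56 ± 0.14, adjusted p = 0.71), Ifit3 (0.89 ± 0.18, adjusted p = 0.47) or Hspa5 (0.63 ± 0.22, adjusted p = 1), so a difference between the lines was not shown for them. Limma called 52 probes, 8 higher and 44 lower, with 2530 at an unadjusted p under 0.05, and median scaling called 193, 4 higher and 189 lower (2.07% in place of 15.4% higher). Using only the 6 arrays compared left 19, and no background correction gave 353, 112 higher and 241 lower. Of the 15 named called genes 14 were lost in some alternative and 1, Egr1, was called in all those run on single genes. Leaving out any 1 of the 6 arrays lowered the count, to 10, 4 and 2 without DHT replicates 1, 2 and 3 and to 4, 6 and 5 without testosterone replicates 1, 2 and 3, and the hypoxia list was called with array weights (camera adjusted p = 0.013) and without DHT replicate 1 (0.00216, in a range of 0.00216 to 0.5).

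Of 9 kidney androgen-responsive genes, 0 were called between DHT and testosterone in either line (0 adjusted over the list alone). Of 32 androgen-response genes of other tissues 0 were called, with 1 higher in wild-type and 2 higher and 1 lower in S42L cells adjusted over the list alone. The following 95% confidence intervals are not adjusted for the number of genes. Odc1 differed by 0.09 (-0.194 to 0.364) in wild-type and 0.20 (-0.0817 to 0.477) in S42L cells. Fkbp5 differed by -0.03 (-0.269 to 0.217) and 0.03 (-0.216 to 0.27), and Tsc22d3 by -0.16 (-0.427 to 0.107) and -0.22 (-0.484 to 0.0497). For Gusb the values were 0.08 (-0.174 to 0.328) and -0.13 (-0.384 to 0.119), and for Lrp2 -0.09 (-0.341 to 0.158) and -0.26 (-0.505 to -0.00561). Pmepa1, which responds to androgens in prostate, stood at 0.58 (0.34 to 0.815, adjusted p = 0.0855) and 0.47 (0.229 to 0.704, adjusted p = 0.089). With no untreated group, a response shared by the androgens cannot be seen. Across 10340 genes the DHT and testosterone differences correlated between the lines (r = 0.453, rho = 0.425), and the lines share no array here. Egln3 was called in both lines, in opposite directions.

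The interaction test asked whether the difference between the lines depended on the androgen, and an additive chip effect cancels in it. Egln3, an oxygen-sensing prolyl hydroxylase induced by hypoxia, was the only probe called of 19480, at -1.63 ± 0.14 (95% confidence interval -1.94 to -1.32, adjusted p = 0.00132). Its mean log2 intensity was 9.004 in wild-type and 7.805 in S42L cells under testosterone, and 7.988 and 8.416 under DHT. Of the 27 hypoxia and glycolysis genes, 1 was lower and 26 were not called (3 lower and 0 higher adjusted over the list alone). Aldoc stood at -0.90 ± 0.14 (adjusted p = 0.185) and Eno2 at -0.61 ± 0.18 (adjusted p = 0.89). The regulatory glycolytic enzyme gene Pfkfb3 was undetected on the 3 wild-type testosterone arrays, at log2 4.514 to 4.907 against 4.846 to 5.37 in S42L cells. Under DHT it stood at 4.559 to 5.813 in wild-type and 4.389 to 5.245 in S42L cells. Its interaction was thus opposite in direction to the list, at values near background. The list median was -0.34 and 24 of 27 members lay below 0. Camera gave adjusted p = 1.56e-11, and adjusted p = 0.0489 with an estimated correlation. Without Egln3, left out after its value was seen, the median was -0.339, 23 of 26 members lay below 0, and camera gave adjusted p = 5.64e-09 and adjusted p = 0.101 with an estimated correlation. The other 24 lists were not called. Limma gave 907 of the 19480 probes an unadjusted p under 0.05, a share below the 0.05 that chance alone would give on average. The sterol list was called without S42L testosterone replicate 1 (camera adjusted p = 0.0401, against 0.25 with all arrays and up to 0.77). With no probe filter, which adds genes below background, the immune marker list was called (camera adjusted p = 0.00625, against 0.854 with the filter and up to 0.927).

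**Figure D3:**
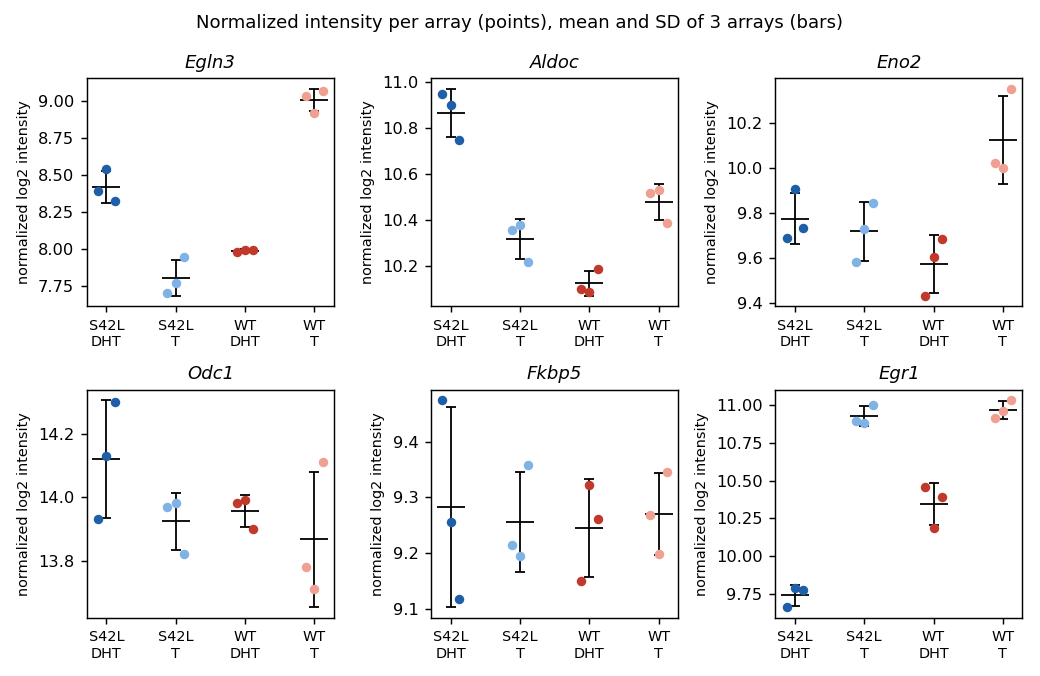
Points are the normalized log2 intensity (y axis) of 6 genes on each of the 3 arrays of the 4 groups (x axis), and bars give the group mean and SD. Egln3 is highest in wild-type cells under testosterone and lowest in S42L cells under testosterone, Aldoc is highest in S42L cells under DHT, Egr1 is lower under DHT in both lines (called in S42L cells, adjusted p = 0.052 in wild-type cells), and the groups overlap for Odc1 and Fkbp5.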

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

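The tests of a single array, of the scaling, without Egln3 and of lists over splits were chosen only after the result was seen, and the interaction test and the splits for called probes were planned. Egln3, an oxygen-sensing prolyl hydroxylase, differed between the lines by an amount that depended on the androgen (interaction -1.63 ± 0.14, adjusted p = 0.00132), and the hypoxia and glycolysis list moved the same way (median -0.34, 24 of 27 genes below 0). The interaction test, a difference between the lines in the same hormone contrast, singled out both. In wild-type cells Egln3 was lower on all 3 DHT arrays than on all 3 testosterone arrays, and in S42L cells it was higher on all 3. No outlier test was run within groups, which hold 3 arrays each.

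As to technical explanations, the list median was -0.26 without wild-type testosterone replicate 3, the array farthest from its group, and between -0.376 and -0.26 over all arrays left out in turn, so that array is not the whole cause. Median scaling left the list at -0.345 relative to all genes, which argues against quantile normalization, and whether the list stands without Egln3 stays open, since camera then gave adjusted p = 5.64e-09 at the preset correlation and adjusted p = 0.101 with an estimated one (range over alternatives 1.53e-15 to 0.0489 for the full list). Of 100 splits of the arrays within the lines, 1, the real one, gave any of the 25 lists as small a camera p. That unadjusted p was 6.26e-13 at the preset correlation, and the smallest camera p of another split was 9.97e-11. A very small camera p at that correlation therefore does not by itself mark the real grouping. Most other splits mix the androgens, and so the chips, within a group, which widens the spread. The hormone contrasts also correlated between the lines, so labels moved in 1 line bring that shared difference into the interaction. The splits are thus unlike the real one, and a share of 1 in 100, the lowest they can give, does not settle whether chance ordered these arrays. Chance differences between cultures also stay open, since replicates may be technical. For called probes 4 splits, the real one among them, reached the real count of 1 and the highest other gave 2, a share under 0.05 that concerns Egln3 and not the list, and a count of 1 is too small to rest on. A hypothesis that remains open is that steroid binding by SHBG may alter the hypoxia program differently under each androgen, which several clones of each variant at a measured oxygen level would test, while oxygen or cell density that differed between single cultures could give the same pattern, and no test here separates them.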

How the results depend on the processing

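Leaving out Egln3 or Cldn2 from a list was chosen only after the result was seen; the other alternatives were planned. The thresholds of 2-fold and of adjusted p under 0.01, 1 probe per gene and the variant and chip terms were applied to counts only. Lists were also not rerun with trend and robust variance or with only the arrays compared. Over the alternatives run on them, no named gene and no list reversed direction with a call. Of gene values 11472 kept their side of the threshold, 321 lost it and 253 gained it, and of list values 2737, 34 and 64. A gene removed by the stricter filter has no value there and is not counted as lost. Of named called genes, 105 of 112 over both androgens were called in every alternative that gave them a value. The same held for 83 of 93 under DHT and 84 of 97 under testosterone. It held for 0 of 7 and 1 of 15 in the hormone contrasts of wild-type and S42L cells, and for Egln3 in the interaction (-1.22 to -1.70). Cell cycle and junction calls held in every alternative run on lists, as did the hypoxia interaction. The latter missed the threshold (0.101) where Egln3 was left out and the correlation estimated at once. Counts over both androgens (7371) became 4332 with 1 probe per gene, 550 at 2-fold or more and 4843 at adjusted p under 0.01. Under DHT (4474) these were 2838, 592 and 2440, and under testosterone (4636) 2878, 621 and 2433, with 8907 under array weights. These follow from fewer probes tested or stricter thresholds, except array weights, where the cause was not tested. Over both androgens median scaling shared 5523 of 6670 calls and the authors' values 7199 of 7265.

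For hormone contrasts the counts (14 in wild-type, 52 in S42L cells) were 66 and 255 with normexp, 71 and 353 with no background correction, 4 and 30 with the authors' values, 9 and 29 with no filter, 33 and 174 with the stricter filter, 95 and 312 with trend and robust variance and 1844 and 628 with array weights. At 2-fold or more they were 7 and 10, at adjusted p under 0.01 3 and 4, and with only the arrays compared, which leaves fewer degrees of freedom, 0 and 19. Median scaling gave 193 in S42L cells. Leaving out 1 array gave 4 to 14 and 2 to 10. The interaction (1) became 2 with normexp, with no background correction, with trend and robust variance and with 1 probe per gene, and 25 with array weights. The correlation of variant contrasts (0.882) was 0.913 with no background correction and with the stricter filter, 0.82 with no filter, 0.852 with array weights and 0.845 to 0.877 with 1 array left out, lowest without wild-type testosterone replicate 2. The cause was not tested for these. Array weights gave wild-type testosterone replicate 3 a weight of 0.216 and replicate 1 5.04. A chip as a block in the hormone contrasts was not run, since each androgen lies on 1 chip.

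With the replicate block the hormone contrasts had 8 and 5 calls, the variant contrasts 4276, 4397 and 7213 and the interaction 1, and under DHT the unfolded protein response and proximal tubule lists were called (0.046 each). Same-numbered arrays did not deviate together (18 pairs, correlations -0.047 to 0.12, median 0.0089, 1 over 0.1), and 3 of 12 arrays matched best with their own number. Signal over background limits dim genes. Median signals of all probes (116.5 to 139.8) lay close to those of undetected probes (108.9 to 129.5). Only 38.2% to 42.4% of probes were detected per array, so this closeness follows from that alone and does not describe the tested probes.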

Other observations

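The tests of fibroblast-like cells, of chip or preparation and of ER chaperones were chosen only after the result was seen. Genes of the amino acid response, targets of the transcription factor ATF4 that no fixed list holds, were higher in wild-type than in S42L cells. Of 25 measured targets, 18 were higher and 1 was lower over both androgens, with a median log2 difference of 0.42. The mitochondrial folate enzymes Mthfd2 (0.81 ± 0.08) and Shmt2 (0.85 ± 0.10), the tRNA synthetases Sars (0.59 ± 0.07) and Wars (0.74 ± 0.09) and the serine synthesis enzyme Psat1 (0.49 ± 0.07) were higher, and the amino acid transporter Slc38a2 was lower (-0.42 ± 0.07). The medians were 0.43 under DHT and 0.42 under testosterone.

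That list was written after Trib3, Ddit3 and Chac1 had been seen to be high and before its own values were computed, and camera with an estimated correlation gave p = 0.00294 (0.00232 under DHT and 0.00461 under testosterone). Within the unfolded protein response list, 12 measured genes downstream of PERK and ATF4 had a median of 0.51, with 8 higher and 0 lower. These 12 were grouped after genes such as Ddit3 had been seen to be high, so their median adds no independent support. The 14 ER chaperones and folding enzymes had a median of -0.143, with 1 higher and 4 lower, which argues against a general rise of ER folding genes. The remaining measured genes of the 38 in that list were in neither part. Over 21 settings the target median lay 0.377 to 0.461 above that of all genes, so it does not turn with the scaling. A hypothesis is that ATF4 may be more active in the wild-type line, which its protein level in several clones of each variant would test. Whether SHBG, the clone or the nutrient state of the cultures is behind it stays open, since the labels name no separate clones of a variant.

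The difference between the lines was large and shared by both androgens (r = 0.882), and the arrays of each line also lay in fixed positions of the chips. The trend over positions within groups gave a median share of 0.0067 of the difference over 550 probes called at 2-fold or more (quartiles -0.1 and 0.12). This argues against a steady trend over the places on the chip. A step between the upper and lower positions would leave no trend within groups, so it cannot be told apart from the line. Fibroblast-like cells in the S42L cultures, which cloning by limiting dilution would remove, could bring Dcn and Col5a1 (-0.70). Of 17 measured fibroblast markers, 4 were lower and 2 higher in wild-type cells. Col1a1, Col1a2 and Col3a1, main collagens of fibroblasts, were picked from that list afterwards, and no others were. They were detected on 3, 0 and 0 of 6 S42L arrays (highest log2 values 5.42, 4.96 and 5.03) and on 5, 1 and 1 of 6 wild-type arrays. Col1a1 was not called lower in wild-type cells, and the other 2 were detected on too few arrays to be tested. The values show no excess of these collagens in S42L cultures. They cannot settle whether fibroblast-like cells were there, since nothing here shows that these probes read the collagens. Of 100 splits of the arrays, 1, the real one, gave 7371 calls and the highest other gave 2. Most other splits mix the lines within a group, which widens the spread, so 2 is not the count expected of lines without a difference. A share of 1 in 100 makes a chance order of these arrays unlikely. It leaves open chance differences between cultures, since replicates may be technical. Differences between clones, a step between chip positions and fibroblast-like or other mesenchymal cells stay open, as does an effect of SHBG steroid binding, untested here.

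The hormone contrasts correlated between the lines (r = 0.453). Over 20988 probes below background on all 12 arrays the correlation was 0.014. Chip, hybridization or preparation of the arrays of 1 androgen and the androgen itself cannot be told apart, because each androgen lies on 1 chip. The 10 possible splits of 6 arrays are too few for a share under 0.05. The real split gave 4474 calls under DHT, 4636 under testosterone, 14 and 52 in the hormone contrasts of wild-type and S42L cells, and the highest other split gave 0 in each, so 1 of 10 reached the real count in each.

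Among the arrays, principal component 1 (50.1% of variance) separated the lines, and wild-type testosterone replicate 3 stood at -39.2 on component 2 (13.9%), where its group's other arrays stood at -5.54 and 8.12. The lowest correlation within a group, 0.983, was between replicates 2 and 3 of that group. Dok3, beside Egln3 the other gene called in opposite directions, had an interaction of 1.15 (adjusted p = 0.12).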
